A study of Dirofilaria repens with 6 samples.

How the data were processed

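RNA sequencing of Dirofilaria repens, a filarial nematode that causes subcutaneous infections in dogs and is carried by mosquitoes, was analysed from 6 libraries. Per the labels, 3 libraries came from L3 larvae and 3 from microfilariae (Mf). L3 is the infective larva that the mosquito passes on, and Mf is the early larva that circulates in the blood of the mammalian host. The series' design text calls the libraries of a stage biological replicates. Replicate numbers were given here in accession order and name libraries only. They pair no L3 library with an Mf library.

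Per the labels' protocols, RNA was extracted with Trizol LS, cleaned on columns and made into stranded TruSeq libraries. The submitters' processing notes name bcl2fastq 2.19, Trimmomatic, STAR 2.5.4b, featureCounts and edgeR, without saying in which order or with which settings. The values used are the deposited counts, whole numbers of reads per gene model that had not been normalized. All rows named a gene model. The name of the assembly, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here, so genes that overlap on opposite strands or that have near-identical copies are uncertain. Among neighbouring tested genes, 25 pairs overlapped on opposite strands and 0 on the same strand.

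The deposited annotation, written with rtracklayer 1.42.1 per the file headers, holds exon positions of 10356 MAKER gene models on 230 scaffolds, with 1-based coordinates. Positions below are on the authors' scaffolds. The files do not pair the gene identifiers with names or products, and no genome was used here. The 31 gene lists fixed before the data were examined (collagens, proteases, heat shock proteins and others) therefore could not be tested. In their place, as also fixed beforehand, 5 classes from the gene models were tested: single-exon genes, genes with 10 or more exons, the shortest and the longest 20% of genes by summed exon length of the longest transcript (up to 507 bases and from 1890 bases), and genes under 100 codons. Of all models, 88.7% had a summed exon length that is a multiple of 3, so the lengths are mostly but not only coding.

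Total counts per library were 428573, 425010 and 1338013 in L3 replicates 1, 2 and 3 and 4057940, 4682688 and 4833502 in Mf replicates 1, 2 and 3. A count of 0 allows up to 3 counts, which is 7.00, 7.06 and 2.24 CPM (counts scaled to a library total of 1e6) in the L3 libraries and 0.739, 0.641 and 0.621 CPM in the Mf libraries. The floor for a gene at 0 in all libraries of a stage was 3 counts over the stage's summed TMM-scaled totals. Intervals are exact 95% binomial intervals. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Apart from this, L3 replicate 2 had genes at 0 that were above its floor in the other L3 libraries.

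L3 was compared with Mf in edgeR 4.0.16 (R 4.3.3) with TMM scaling, the filterByExpr filter, glmQLFit and the two-sided glmQLFTest on stage alone, all 6 libraries in 1 fit. P-values were adjusted by Benjamini-Hochberg over all tested genes at a threshold of 0.05. A second test (glmTreat, same fit) asked for a change of more than 2-fold. Log2 fold changes are L3 over Mf. Their standard errors were derived from the F statistic. CPM of single genes are TMM-scaled, and sums over scaffolds and the stage-restricted rule use CPM of the library total. Gene classes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and adjustment over the 5 classes, and again with an estimated correlation. Differences given for classes are mean edgeR log2 fold changes of the class minus those of the other genes. The camera p-values do not test these means, and the 2 can differ in direction. A gene was called stage-restricted when it had at least 1 CPM in all 3 libraries of a stage and at most 3 counts in total in the other stage. Adjacent tested genes on a scaffold were compared with 10000 random placements of the calls or ranks over the tested genes (one-sided permutation test, smallest possible p 0.0001). Scaffolds with at least 10 tested genes were tested for an excess of calls by a one-sided hypergeometric test, adjusted over scaffolds. These scaffold tests were added after the data had been examined. Genes and pairs of genes are not independent replicates.

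Without names, the rule fixed beforehand for single genes gave 2 identifiers per direction, those with the largest fold change among genes past the 2-fold test whose 3 libraries of a stage all lay above the other stage and whose mean was at least 10 CPM, plus the gene with the highest mean level in each stage, described by position. All other genes are given as groups.

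The tests were checked on simulated counts with the libraries' own totals and with genes changed by known folds. The spread was set per gene and shared by all libraries. The excess of genes at 0 in L3 replicate 2 was not simulated, so errors under such unequal libraries were not checked. With all 6 libraries, the edgeR test against no change recovered 0 of 67 genes changed 2-fold, 2 of 67 changed 4-fold and 33 of 66 changed 16-fold. It called 1 of 7252 unchanged genes. The 2-fold test recovered 0, 1 and 24 of these changed genes. Without L3 replicate 2 the test against no change recovered 7 of 67, 51 of 67 and 63 of 66, and called 9 of 7963 unchanged genes. The 2-fold test then recovered 0, 25 and 60. The permutation test of neighbours gave p = 0.139 for calls placed at random and 0.0001 for calls placed in runs, each in a simulation on 7764 genes.

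Chosen before the data were examined were other settings for each result, namely RLE and upper-quartile factors, no filter on low counts, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, each of the 6 libraries left out in turn, other limits and thinned counts for stage-restricted genes, other distances, strands and calls for neighbours, and the estimated correlation. Added after the data had been examined were limma-voom with sample quality weights, thinning of all libraries to the smallest total for the tests of genes and gene classes, and leaving out scaffolds with few introns, for neighbours also together with L3 replicate 2. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.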

Results

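Gene expression was measured by RNA sequencing in 2 stages of Dirofilaria repens, infective L3 larvae and microfilariae, with 3 libraries each. The series title names a comparison of transcriptomes between stages of this parasite. Of 10356 gene models, 9834 had at least 1 count in some library and 4152 in all 6. The L3 libraries held 428573, 425010 and 1338013 counts and the Mf libraries 4057940 to 4833502. Genes with at least 1 count numbered 7933, 4312 and 8612 in L3 replicates 1, 2 and 3 and 9314 to 9405 in the Mf libraries. The 10 most abundant genes of a library took 13.0% ± 2.08 (SD, n = 3) of the counts in L3 and 8.91% ± 1.19 (SD, n = 3) in Mf. With 3 libraries against 3, an exact permutation test of such a value cannot go below p = 0.1, and none was made.

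The Mf libraries, which held more counts, correlated more closely with one another than the L3 libraries did. Fewer counts can lower r by counting error alone, and r was not compared at equal depth. Across genes, Pearson's r of log2(CPM + 1) was 0.987 to 0.991 between Mf libraries. It was 0.913 between L3 replicates 1 and 3, but 0.660 and 0.673 between L3 replicate 2 and these. With the Mf libraries, L3 replicate 2 had r of 0.573 to 0.577 and the other L3 libraries 0.790 to 0.831. Only as a check for a library that repeats another, the chi-square statistic per degree of freedom was at least 10.4 for each pair, so all 6 were counted separately. L3 replicate 2 had 6044 genes at 0 counts at nearly the total of L3 replicate 1, which had 2423. Among genes at 10 to 30 CPM in L3 replicates 1 and 3 on average, 61.6% were at 0 in L3 replicate 2. This share was 36.1% at 30 to 100 CPM, 11.5% at 100 to 300 CPM and 1.72% at 300 to 1000 CPM.

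**Figure D1:**
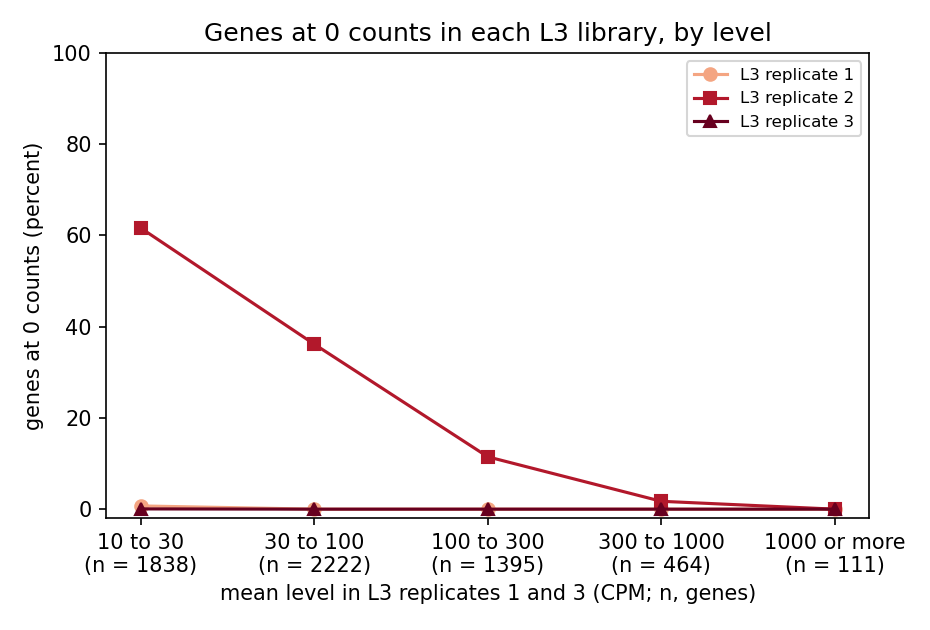
Share of genes at 0 counts (vertical axis, percent) in each of the 3 L3 libraries, for genes grouped by their mean CPM in L3 replicates 1 and 3 (horizontal axis, number of genes in brackets). L3 replicate 2 falls from 61.6% in the lowest class to 0% in the highest, while L3 replicates 1 and 3, which also set the classes, stay at or below 0.707%.

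Against Mf, 317 genes were higher and 177 lower in L3 by more than 2-fold, of 7764 genes tested (edgeR, adjusted p under 0.05). The 317 genes higher in L3 took 32.7% ± 3.93 (SD, n = 3) of the counts in L3 libraries and 3.81% ± 0.337 (SD, n = 3) in Mf libraries. Their median level was 338 CPM in L3 and 7.63 CPM in Mf. The 177 genes lower in L3 had a median of 0.822 CPM in L3 and 25.1 CPM in Mf, and included the most abundant gene of Mf. They took 0.335% ± 0.112 (SD, n = 3) of the counts in L3 and 6.44% ± 0.567 (SD, n = 3) in Mf, and 58 of them had 0 counts in every L3 library. Of the 177, 24 lay on 3 scaffolds with few introns described below, whose origin is open. Against no change, 497 genes were higher and 448 lower in L3, with 37 of the 448 on these 3 scaffolds. The counts of genes higher and lower in L3 depended on single libraries. Without L3 replicate 2, 953 genes were higher and 652 lower beyond 2-fold, and 1725 and 1674 against no change. This fit still called 312 of the 317 and 177 of the 177 genes beyond 2-fold in the same direction. Leaving out another library lowered the counts beyond 2-fold to 263 and 15 without L3 replicate 1 and 209 and 31 without L3 replicate 3. They were 175 and 35 without Mf replicate 1, 185 and 38 without Mf replicate 2, and 178 and 32 without Mf replicate 3. Against no change, these 5 fits called 243 to 417 genes higher and 85 to 100 lower in L3.

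**Figure D2:**
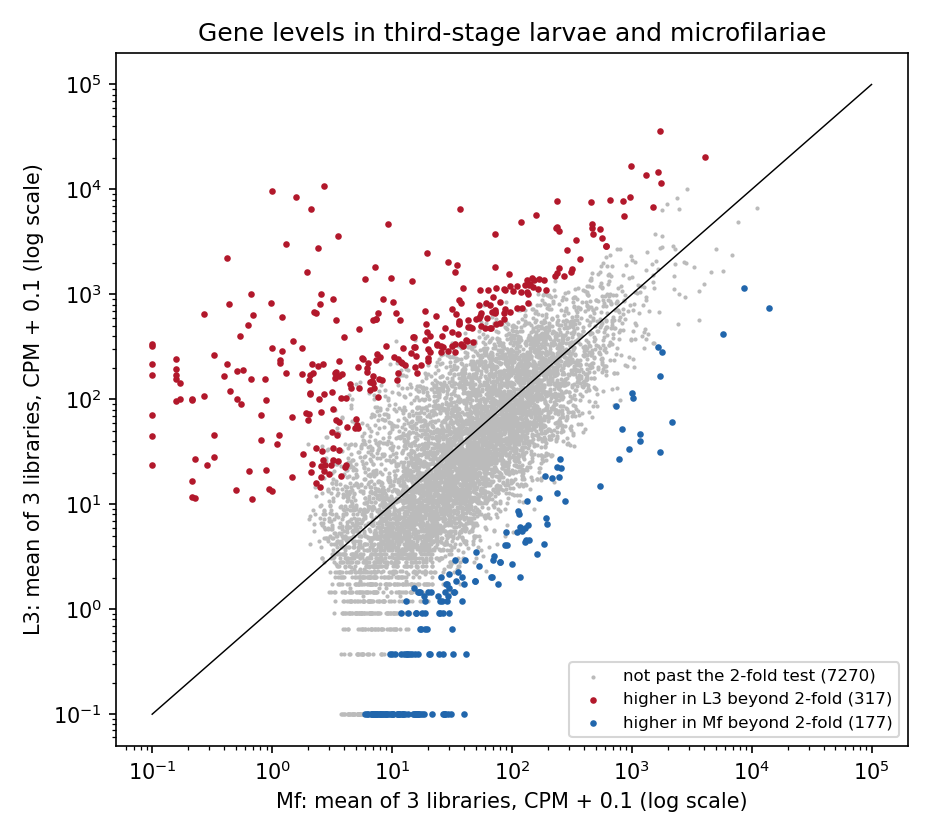
Mean level of each of the 7764 tested genes in Mf (horizontal axis) and L3 (vertical axis), as TMM-scaled CPM + 0.1 over 3 libraries per stage, both on log scales, with the line of equal levels. The 317 genes higher in L3 beyond 2-fold (red) spread up to high levels in L3, while the 177 genes higher in Mf (blue) have a median of 25.1 CPM in Mf.

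The gene maker-000027F-augustus-gene-0_0 has 6 exons on the plus strand of scaffold 000027F (10618 to 12558). It had the largest fitted fold change towards L3 among genes that met the rule for naming. It had 9720 CPM ± 2218 (SD, n = 3) in L3 and 0.906 CPM ± 0.428 (SD, n = 3) in Mf, from 16464 and 15 counts. Its log2 fold change was 13.32 (SE 0.68, edgeR adjusted p = 3.3e-07). The next, maker-000100F-augustus-gene-0_10, with 6 exons on the plus strand of scaffold 000100F (211437 to 213984), had 46.5, 812 and 160 CPM in L3 replicates 1, 2 and 3. It had 0 counts in all Mf libraries and was at least 1860-fold higher in L3 (edgeR adjusted p = 0.00119). This bound was 566-fold without L3 replicate 2 and 1198-fold without Mf replicate 2. With only a lower bound, the order of these 2 genes is open. The fitted log2 fold change of the second was the larger with DESeq2 (13.67 against 13.58). The same held without L3 replicate 1 and without L3 replicate 3. Of the genes that met this rule, 309 were higher in L3. The 10 with the largest fitted fold change among these had 170 to 10834 CPM in L3 and 0 to 2.59 CPM in Mf, with 3 to 12 exons.

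Towards Mf, the gene augustus-000182F-processed-gene-0_1, with 2 exons on the plus strand of scaffold 000182F (26567 to 26912), led the genes that met the rule by fitted fold change. It had 40.1 CPM ± 3.84 (SD, n = 3) in Mf and 0 counts in all L3 libraries, and was at least 25.4-fold higher in Mf (edgeR adjusted p = 0.00923), or 9.08-fold without L3 replicate 3. The next was augustus-000190F-processed-gene-0_33, a single-exon gene on the minus strand of scaffold 000190F (43560 to 44476). It had 31.2 CPM ± 15.4 (SD, n = 3) in Mf and 0 counts in L3, and was at least 19.7-fold higher in Mf (edgeR adjusted p = 0.0117), or 7.06-fold without L3 replicate 3. Its adjusted p was 0.0502 without L3 replicate 1 and 0.0656 without L3 replicate 3, and ranged from 1.0e-05 to 0.0656 over all alternatives. Its scaffold is one of 3 with few introns whose counts were nearly all from Mf. Of the 148 genes that met the rule towards Mf, the 10 with the largest fitted fold change had 17.7 to 40.1 CPM in Mf and 0 counts in L3. Their folds are thus only bounded from below, and their order is open. Of these 10, 2 lay on those 3 scaffolds.

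The most abundant gene in L3, with 4 exons on the plus strand of scaffold 000044F (610504 to 611332), had 36421 CPM ± 33800 (SD, n = 3), a spread close to the mean. It had 23906, 74693 and 10662 CPM in L3 replicates 1, 2 and 3. In Mf replicates 1, 2 and 3 it had 1373, 3485 and 308 CPM. Its log2 fold change was 4.40 (SE 0.88, edgeR adjusted p = 0.00923), but 3.29 without L3 replicate 2 and 5.49 without Mf replicate 2. Its adjusted p ranged from 0.000123 to 0.0447 over all alternatives. The most abundant gene in Mf, with 3 exons on the plus strand of scaffold 000092F (270893 to 271559), had 14081 CPM ± 1253 (SD, n = 3) in Mf and 748 CPM ± 78.1 (SD, n = 3) in L3. Its log2 fold change was -4.23 (SE 0.39, edgeR adjusted p = 4.0e-05). The 5 most abundant genes of L3 were all higher in L3 than in Mf (edgeR, adjusted p under 0.05). Of the 5 most abundant genes of Mf, 3 were higher in Mf and 2 did not pass the test.

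Transcripts restricted to a stage were sought as genes with at least 1 CPM in all 3 libraries of a stage and at most 3 counts in the other stage. In Mf, 798 genes met this rule and in L3 27 genes. In L3, 3 counts are 1.37 CPM of the summed library totals, so a gene at 1 CPM in both stages can meet the Mf rule. Of the 798 genes, 119 were called beyond 2-fold, as were 23 of the 27, and 315 remained at 5 CPM. When 0 counts were required in the other stage, 287 genes were Mf-restricted and 9 L3-restricted. The L3-restricted genes had a median of 70.2 CPM in L3, and 9 of them exceeded 100 CPM. The Mf-restricted genes had a median of 5.17 CPM in Mf, and 1 of them exceeded 100 CPM. These levels are not comparable, because the L3 rule needs counts in L3 replicate 2. That library was at 0 for 61.6% of genes at 10 to 30 CPM in the other L3 libraries. At 30 to 100 CPM the share was 36.1%. Genes at low levels therefore seldom could meet the L3 rule. Single-exon genes made up 80 of the 798 Mf-restricted genes, 0 of the L3-restricted genes and 422 (4.07%) of all gene models. These groups were not matched on level, and with 27 L3-restricted genes a share of 0 shows little. Of the 798, 59 lay on 3 scaffolds with few introns described below, 23 of them with a single exon, against 57 (7.71%) of the 739 others. Absence was read from 2191596 counts in L3 and from 13574130 counts in Mf. Thinned to the smallest library total, 102 genes were L3-restricted and 926 Mf-restricted. In thinned libraries 3 counts are 7.06 CPM, so 1 count in each library of a stage meets the 1 CPM limit. A gene with 1 count in every library then meets both rules, and these numbers do not show restriction at equal depth. Without L3 replicate 2, 95 genes were L3-restricted, and without L3 replicate 3, 2142 were Mf-restricted.

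Of the 5 classes of gene structure, only single-exon genes passed the test between stages, and they were lower in L3. Their mean edgeR log2 fold change was -0.86 relative to the other genes. The median was -0.84 in the class and -0.32 in the other genes. Fitted folds of genes at 0 in L3, which are only bounded, enter the means. The camera test gave an adjusted p of 0.00751 with the preset correlation and 0.966 with an estimated correlation. Of 143 tested single-exon genes, 8 were higher and 26 lower in L3, and 109 did not pass (10 higher and 38 lower when adjusted over the list alone). Of the 26 that were lower, 8 lay on the 3 scaffolds with few introns. Leaving out all scaffolds with few introns, a step chosen after the data were examined, gave a difference of -0.39 (adjusted p = 0.0904). Thinning all libraries to the smallest total, also chosen afterwards, gave -0.19 over 51 such genes (adjusted p = 0.312). The difference was -0.54 (adjusted p = 0.106) without Mf replicate 1, -0.64 (adjusted p = 0.0576) without Mf replicate 2 and -2.08 (adjusted p = 9.6e-05) without L3 replicate 3. Over all alternatives the adjusted p ranged from 9.6e-05 to 0.966.

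Genes with 10 or more exons differed from the other genes by 0.12 (adjusted p = 0.758), with 166 higher and 105 lower of 3200 tested (139 and 73 when adjusted over the list alone). The longest 20% by summed exon length differed by 0.05 (adjusted p = 0.758), with 94 higher and 70 lower of 1965 (79 and 51 adjusted over the list alone). The shortest 20% differed by 0.02 (adjusted p = 0.860), with 76 higher and 85 lower of 997 (91 and 110 adjusted over the list alone). Genes under 100 codons differed by -0.22 (adjusted p = 0.611), with 10 higher and 23 lower of 239 (14 and 31 adjusted over the list alone). Leaving out 1 library moved these 4 differences, in the order given, to between -0.09 and 0.54, -0.14 and 0.42, -0.50 and 0.26, and -1.05 and -0.16. None of the 4 classes passed in any alternative. The median log2 fold change of the genes outside a class lay between -0.34 and -0.32, so a class with a positive difference can still have a negative median.

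Genes that differed between stages lay next to one another more often than random placement gave. Of 7538 adjacent pairs of tested genes, 50 were called beyond 2-fold in the same direction, 33 towards L3 and 17 towards Mf. Without the scaffolds with few introns these were 33 and 5 (ratio 2.43 to random placement). Without L3 replicate 2 there were 198 and 85 pairs, and leaving out any other library left 2 towards Mf and 18 to 24 towards L3. The 50 pairs were 3.05 times the mean of 16.4 pairs under random placement (one-sided permutation p = 0.0001, the smallest possible). The ratio was 1.84 without L3 replicate 2, 5.49 without Mf replicate 1, 5.30 without Mf replicate 2 and 6.02 without Mf replicate 3, each at the same p. Across adjacent genes, Spearman's rho of the log2 fold changes was 0.111 (permutation p = 0.0001). For pairs at most 1000 bases apart it was 0.252 on the same strand (794 pairs) and 0.108 on opposite strands (786 pairs). For pairs more than 5000 bases apart it was 0.105 and 0.0700.

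There were 9 runs of at least 3 adjacent tested genes called beyond 2-fold in the same direction, 4 towards L3 and 5 towards Mf. Runs were not among the results fixed beforehand. Their number was not compared with random placement. The longest towards L3 held 4 genes on scaffold 000049F (360376 to 425710), which summed to 2157 CPM ± 631 (SD, n = 3) in L3 and 38.2 CPM ± 2.08 (SD, n = 3) in Mf. The most abundant held 3 genes on the plus strand of scaffold 000188F (28959 to 49764), with 24049 CPM ± 14758 (SD, n = 3) in L3 and 1738 CPM ± 96.0 (SD, n = 3) in Mf. On scaffold 000092F (267944 to 271559), 3 genes that include the most abundant gene of Mf summed to 23890 CPM ± 2809 (SD, n = 3) in Mf and 1947 CPM ± 481 (SD, n = 3) in L3. The other Mf runs lay on scaffolds 000059F (3 runs) and 000107F, both among the scaffolds with few introns described below, whose origin is open. The number of runs depended on single libraries. There were 46 without L3 replicate 2, where all genes of the 9 runs stayed called beyond 2-fold. Leaving out any of the other 5 libraries left 2 to 4 runs, and 1 of the 5 Mf runs and 0 to 3 of the 4 L3 runs kept all their genes called.

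Calls towards Mf exceeded the expected number on 2 of 142 scaffolds, a result that depended on single libraries. On scaffold 000059F, 16 of 25 tested genes were higher in Mf beyond 2-fold where 0.570 were expected (hypergeometric test across genes, adjusted p = 6.5e-19). On scaffold 000107F, 6 of 14 were, with 0.319 expected (adjusted p = 2.4e-05). Without L3 replicate 2, 18 of 33 and 8 of 19 were, and scaffold 000025F also passed (12 of 55, 4.27 expected, adjusted p = 0.0432). Leaving out any of the other 5 libraries, scaffold 000107F did not pass, and scaffold 000059F passed only without Mf replicate 2 (3 of 21, adjusted p = 0.0223). Scaffold 000092F passed in 4 of these 5 fits. Calls towards L3 exceeded the expected number on 0 of 142 scaffolds at an adjusted p under 0.05 (hypergeometric test, 4 scaffolds at an unadjusted p under 0.05). Scaffold 000188F was not among the 142, since it held 8 tested genes, under the minimum of 10, and 4 of the 8 were higher in L3. Without each of L3 replicates 1, 2 and 3 it held 10 tested genes and passed (adjusted p = 0.0275, 0.0367 and 0.0114). Scaffold 000013F passed only without L3 replicate 2 (adjusted p = 0.0367). Scaffolds 000059F and 000107F had few introns. Scaffolds with at least 10 genes and a median under 2 introns per kb of exon, a rule set after the data were examined, were these and scaffolds 000190F and 000249F. The medians were 0.775, 0.880, 1.20 and 1.34 introns per kb on scaffolds 000059F, 000107F, 000190F and 000249F, against 5.93 on all other scaffolds. Of these 4, scaffolds 000059F, 000107F and 000190F were grouped because every Mf library exceeded every L3 library more than 2-fold in CPM. Together these 3 scaffolds held 89 genes, of which 34 (38.2%) had a single exon. Their summed level was 1341 CPM ± 538 (SD, n = 3) in Mf and 33.5 CPM ± 8.11 (SD, n = 3) in L3. The Mf replicates 1, 2 and 3 had 1948, 923 and 1151 CPM, and the L3 replicates 25.7, 32.9 and 41.9 CPM. Scaffold 000249F, with 11 genes, had 1229 CPM ± 56.1 (SD, n = 3) in Mf and 1419 CPM ± 523 (SD, n = 3) in L3, a difference within the spread of the L3 libraries.

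**Figure D3:**
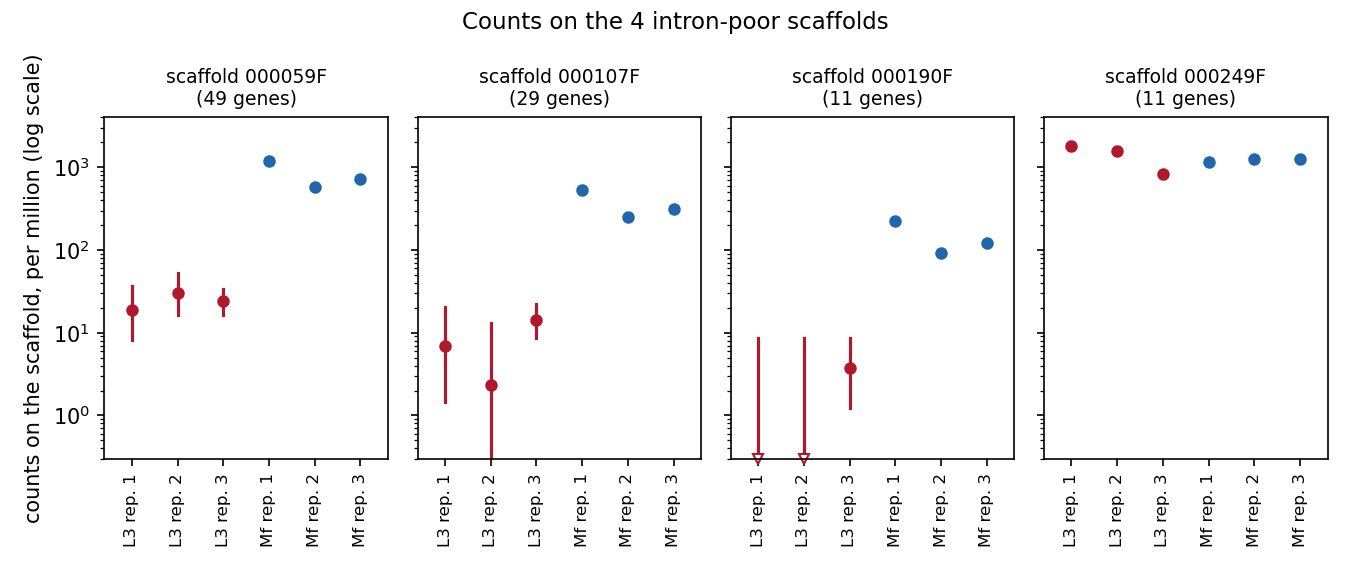
CPM of the library total (vertical axis, log scale) on each of the 4 scaffolds with few introns, in each L3 library (red) and Mf library (blue), with exact 95% binomial intervals that cover counting error only. Open triangles at the lower edge mark 0 counts. Scaffolds 000059F, 000107F and 000190F were grouped because every Mf library lies above every L3 library on them. Mf replicate 1 lies above the other Mf libraries there, while the stages overlap in level on scaffold 000249F.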

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

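The fits with sample quality weights, the tests of genes and gene classes on thinned libraries and the fits without scaffolds with few introns were chosen after the results were seen. So were the scaffold tests and runs of genes without single libraries. Of the 945 genes called against no change, 283 to 943 stayed called in the 14 alternative fits, and none turned direction where tested (552 were tested after thinning). These genes were picked in the main fit and the alternatives reuse its libraries, so a change of direction was unlikely beforehand. No paired analysis was possible because the labels give no replicate numbers shared between stages. Neighbouring calls exceeded random placement by a ratio of 1.79 to 6.02, the lowest without both L3 replicate 2 and the scaffolds with few introns, and rho stayed between 0.0775 and 0.181, in all alternatives. For single genes, the adjusted p of the single-exon gene named on scaffold 000190F was 0.0502 and 0.0656 without L3 replicate 1 and without L3 replicate 3, and the other named genes stayed past the threshold in all alternatives.

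The counts of calls did depend on the test. DESeq2 called 1234 genes higher and 1602 lower in L3, and 435 and 281 beyond 2-fold, with 52 and 203 genes left without an adjusted p in the 2 tests. Limma-voom called 257 and 267, and 136 and 53 beyond 2-fold, and with sample quality weights 1095 and 1161, and 471 and 210 beyond 2-fold. These weights gave L3 replicate 2 a weight of 0.0484. RLE factors gave 375 and 268 beyond 2-fold. The cause of these differences was not tested. With all libraries thinned to the smallest total, 5274 genes could be tested, with 333 higher and 131 lower in L3, and 230 and 59 beyond 2-fold. Leaving out 1 library gave 243 to 1725 genes higher and 85 to 1674 lower, and beyond 2-fold 175 to 953 higher and 15 to 652 lower. The highest values came without L3 replicate 2, where the biological coefficient of variation was 0.248 in place of 0.615.

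L3-restricted genes numbered 9 when 0 counts in Mf were required, 102 after thinning and 27 to 95 without 1 library. The thinned rule is met by 1 count per library, so the 102 genes do not show restriction at equal depth. Mf-restricted genes numbered 315 at 5 CPM, 287 when 0 counts in L3 were required and 825 to 2142 without 1 library. For single-exon genes the difference was -0.86 with an estimated correlation (adjusted p = 0.966), -0.39 without the scaffolds with few introns (adjusted p = 0.0904), -0.19 after thinning with 51 such genes tested (adjusted p = 0.312) and -2.08 to -0.54 without 1 library (adjusted p from 9.6e-05 to 0.106). The 50 most abundant genes, in place of 10, took 28.6% of the counts in L3 and 19.5% in Mf. Depth limits what a 0 can show in L3, up to 7.06 CPM of the library total from counting error alone in L3 replicate 2. On TMM-scaled CPM this floor is higher, since the TMM factor of L3 replicate 2 was 0.639. In that library 36.1% of genes at 30 to 100 CPM in the other L3 libraries were at 0.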

Other observations

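Tests in this part were chosen after the results were seen, except those of a mislabelled library, of neighbours that do not overlap, and of neighbour pairs over other splits of the libraries.

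Without L3 replicate 2, calls towards L3 exceeded the expected number on 2 of 153 scaffolds, which held a small part of the 953 such calls. On scaffold 000188F, 6 of 10 tested genes were higher in L3 beyond 2-fold where 1.13 were expected (hypergeometric test across genes, adjusted p = 0.0367). On scaffold 000013F, 31 of 148 were, with 16.8 expected (adjusted p = 0.0367). With all 6 libraries scaffold 000013F did not pass, and scaffold 000188F was not tested, since its 8 tested genes were under the minimum of 10. The most abundant gene of L3 also varied within Mf, from 308 CPM in Mf replicate 3 to 3485 CPM in Mf replicate 2.

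L3 replicate 2 had 6044 genes at 0 counts. Lower depth alone is argued against, because L3 replicates 1 and 3 thinned to its total had at most 2445 genes at 0 in 40 draws. A mislabelled Mf library is argued against as well. Of 52 genes with at least 300 CPM on average in L3 replicates 1 and 3 and more than 10 times the level of every Mf library there, 98.1% were above every Mf library in L3 replicate 2. A low number of starting molecules may explain the pattern and stays open, since the share at 0 was 61.6% among genes at 10 to 30 CPM and fell in each higher class of level, and no biological explanation was tested.

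Scaffolds 000059F, 000107F and 000190F were higher in Mf as a block. They were grouped because every Mf library exceeded every L3 library more than 2-fold in CPM, so a ratio above 2 was set by the choice and shows nothing. The lowest Mf library was 22.1 times the highest L3 library in summed CPM. Counting error in shallow L3 libraries is argued against only by the size of this gap. The upper limits of the exact binomial intervals were at most 55.3 CPM in L3, and the lower limits at least 896 CPM in Mf. These limits cover counting error only. A candidate explanation is that these scaffolds hold sequence of another organism that was present in the Mf samples in unequal amounts. Over 52 genes with enough counts, Mf replicate 1 exceeded the mean of the other Mf libraries by a median of 0.97 on the log2 scale (SD 0.37), while the highest median of 10000 lists of other genes matched on level was 0.19. This ratio was already visible in the summed levels, and genes of the worm that are active together in Mf, to a different degree in each library, would give it too. It does not separate the 2 explanations, which both stay open, and no sequence was searched.

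Close neighbours on the same strand had more similar stage differences than those on opposite strands. Similarity of a region shared by both strands is argued against as the whole cause, since rho differed by 0.144 between same-strand and opposite-strand pairs at most 1000 bases apart (two-sided permutation p = 0.0049). The scaffolds with few introns held few of these pairs and could add little to the pattern. Without them, 789 of the 794 same-strand pairs remained, with rho of 0.244 (permutation p = 0.0001). With so few pairs removed, rho was unlikely to end. Shared transcription of adjacent genes, known from other nematodes as operons, may explain the pattern. It cannot be told apart from gene models that split a gene or from reads running on into the next gene. The 794 same-strand pairs include 0 that overlap, and their rho of 0.252 (permutation p = 0.0001) is what both predict. Near-identical copies that lie next to one another, whose counts are uncertain here, were not examined, so other explanations stay open.

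The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 945 genes against no change, 494 beyond 2-fold and 50 neighbour pairs, and for each of these it was the 1 split with a value as large. The highest of the other splits was 0 for all 3 (edgeR), with 143 to 239 genes at an unadjusted p under 0.05 against 2330 in the real split. Each other split holds libraries of both stages on both sides, so the stage difference adds to the spread and few calls were likely beforehand. Without called genes there can be no called pairs. No conclusion is drawn from this contrast. For gene structure classes the real split gave 1 class past the threshold, and 4 of the 10 splits gave as many, the highest of the other splits being 1.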
